A study of Mus musculus with 10 samples.

How the data were processed

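Liver RNA of 10 male mice of the inbred strain C57BL/6NCrSlc was measured on 10 one-colour Agilent microarrays, 1 array per mouse. Per the labels, every mouse received a diet high in cholesterol, and 5 of them also drank an extract of mulberry leaves for 4 weeks. The 5 mice without the extract are called control and the 5 with it mulberry. Each array was hybridised with Cy3-labelled cRNA made from 500 ng of RNA, per the labels' protocols. The labels gave each group the numbers 1 to 5 and stated no pairing between them.

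The deposited scanner tables held the fluorescence intensity of each spot, corrected for background within the array and not normalized between arrays, per the file headers. They were made with Agilent Feature Extraction 10.1.1.1, per the submitters' processing notes. A deposited table of the whole series held a linear intensity per gene symbol and array. Its scale was read from its values, and how the authors normalized it and combined probes is not given in the sources used here. Its columns had median log2 values of 5.14, 5.15, 5.18, 5.10 and 5.17 for control 1 to 5 and of 5.31, 5.17, 5.11, 5.19 and 5.24 for mulberry 1 to 5. This table served as an alternative, and 0 columns of either kind of file were left unused for belonging to another sample.

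Each array carried 43379 spots that were not controls and 41174 different probes. Spots flagged as outliers were left out, replicate spots of a probe were averaged, and 46 probes without a value on some array were dropped, which left 41128. No spot was saturated. Probes were named by matching their transcript accessions, without versions, to a RefSeq gene table of mouse assembly GRCm38.p6. A match was found for 25070 probes (61.0%), which gave 17295 gene symbols; 15342 other names were kept as the arrays' design gave them. The file headers named an older assembly, so no coordinates are given.

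The main values were log2 of the processed intensity minus the 75th percentile of that quantity on the same array. A level of 0 is thus the 75th percentile of its array, and levels are not compared between genes. A gene was represented by its probe with the highest mean over the 10 arrays. Genes were tested where that probe was well above background on at least 4 of 5 arrays of at least 1 group, which held for 17847 of 32636 names. Differences are mulberry minus control on the log2 scale, with the standard error (SE) of the fit. They were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Tables were read with the package data.table (version 1.17.8) and plots drawn with matplotlib 3.10.9 in Python 3.11.15. Probes can cross-hybridise between close relatives such as Hsd3b1 and Hsd3b5, and their values are less certain for that reason.

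There were 28 gene lists of pathways and cell types, of which 27 had at least 5 members among the genes tested. They covered cholesterol synthesis, sterol regulation and uptake, sterol efflux and LXR targets, bile acids, fatty acid synthesis, fatty acid oxidation, lipid droplets, lipoproteins, drug metabolism, antioxidant genes, glucose metabolism, the acute phase, endoplasmic reticulum stress, the interferon response, the cell cycle, the clock, immediate early genes, sex-biased liver genes, and markers of hepatocytes, macrophages, lymphocytes, stellate, endothelial, bile duct, red, acinar and fat cells. Each list was tested against all other genes with camera at a preset correlation of 0.01 between its genes, adjusted over the lists. Because genes of one pathway vary together from mouse to mouse, camera with an estimated correlation, fry (a rotation test of the list itself) and an exact two-sided permutation test of the list mean over the 252 assignments of arrays to groups were also run. The permutation test ignored scan day and slide, so its p values assume exchangeable arrays. List differences are given as the median over members or as the difference between group means of the list mean per array; the SE of the second came from the spread between arrays. Gene calls were also counted after adjustment over the list alone. Some lists shared members, so the lists are not independent of each other.

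The grouping, the fits, the gene lists, the counts over other splits of the arrays and the alternatives other than those named below were fixed before the data were examined. The text may name the genes past the threshold with the largest changes or, with none past it, the 5 smallest p in each direction, up to 4 members of each list by absolute change, and 19 genes of sterol, bile acid and fatty acid metabolism whatever their values; not every gene so allowed is reported. The alternatives were other scalings (the median, quantile normalization, the 75th percentile over probes detected on all arrays), normexp background correction with an offset of 50, the deposited series table, other filters, the mean over the probes of a gene, blocks for replicate number, slide and scan day, array weights, a trended and robust fit, and leaving out each array in turn. The scanner tables held no mean signals, so normexp was run on median signals. Added after seeing the data were fits without mulberry 1 and mulberry 5, within each scan day, within slide 3 and with the slide as a random block, and the list means tested by permutation or taken relative to hepatocyte markers.

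The arrays came from 4 slides scanned on 2 days. Slide 1 held control 2, 3 and 5 and slide 2 held mulberry 3 and 5, all scanned on day 1. Slide 3 held control 1, control 4 and mulberry 1, and slide 4 held mulberry 2 and 4, all scanned on day 2. Slide 3 was the only one with both groups, so a fixed slide block rests on those 3 arrays, with 1 mulberry array assumed to vary like the others. Precision was limited by the number of arrays. The gene test was checked on simulated data for the 17847 genes with the measured spread, where 200 genes were changed by known folds. It recovered 12.0% of the genes changed 1.5-fold, 56.0% of those changed 2-fold, 76.0% at 3-fold and 92.0% at 4-fold in the right direction, with 4 unchanged genes called. Of 4 lists shifted by 0.3 in a simulation with independent genes, 4 were recovered, and 0 of 22 lists sharing no shifted gene were called. That simulation does not test the preset correlation for lists whose genes vary together between mice.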

Results

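Liver transcript levels were measured in 5 mice on a high-cholesterol diet and in 5 mice that also drank mulberry leaf extract for 4 weeks. The series title frames the study around lowered cholesterol synthesis in hypercholesterolemic mice, and the design has a single comparison, mulberry against control. Between 54.4% and 62.4% of the probes of an array were well above background. The 75th percentile of the processed signal ranged from 152.8 to 283.3 over the arrays, and log2 levels of any 2 arrays correlated across genes with r between 0.940 and 0.993.

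With mulberry, 0 of 17847 genes passed the limma test (smallest adjusted p = 0.506). Unadjusted p was under 0.05 for 924 genes, 515 higher and 409 lower, where 892 are expected with no difference. The higher share of these was 55.7%. It was 8.57% under median scaling, 32.0% under quantile normalization and 31.3% in the deposited series table. In the other direction, it was 79.0% with no filter on dim probes, 80.5% without mulberry 1 and 88.8% without mulberry 1 and 5. A test of every probe also gave 0 calls among 23243 probes. Among the genes with small p in the lower direction was Adgrf1, an adhesion receptor (-1.41 ± 0.29, SE). The collagenase gene Mmp13 (-1.96 ± 0.44), the steroid dehydrogenase gene Hsd3b1 (-0.97 ± 0.22) and the keratin gene Krt13 (-0.75 ± 0.18) were also lower. Mmp13 was dim, well above background on 2 of 5 mulberry arrays, and its difference was 0.02 after normexp correction. In the higher direction stood Rnf208 (1.03 ± 0.16), the claudin gene Cldn9 (0.76 ± 0.13), the sulfotransferase gene Chst3 (0.84 ± 0.15), the channel gene Cngb1 (0.81 ± 0.16) and Siglecg (0.81 ± 0.16), a sialic acid receptor of B cells. For Chst3 and for Krt13, 1 of 2 probes went in the stated direction. Rnf208 passed the test without mulberry 1 (adjusted p = 0.0359) and with array weights (adjusted p = 0.0150).

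Genes of cholesterol synthesis were lower with mulberry as a group. Of 19 measured members 15 were lower and 4 higher, with a median of -0.34, and 0 passed the gene test, also when adjusted over the list alone. The largest differences were in Tm7sf2 (-0.88 ± 0.38), Cyp51 (-0.78 ± 0.24), Nsdhl (-0.76 ± 0.23) and Fdps (-0.61 ± 0.21), which code for enzymes of the mevalonate and post-lanosterol steps. Hmgcs1 (0.09 ± 0.21) and Sqle (0.21 ± 0.35) had differences within their errors. Without mulberry 1 and mulberry 5, Tm7sf2 was at -0.27 ± 0.22, Cyp51 at -0.48 ± 0.22, Nsdhl at -0.85 ± 0.28 and Fdps at -0.44 ± 0.23. Hmgcs1 was then at 0.33 ± 0.20 and Sqle at -0.34 ± 0.21. The list passed camera with the preset correlation (adjusted p = 3.8e-06) and not with an estimated correlation (adjusted p = 0.401). The list mean was -0.32 ± 0.12 (SE over arrays), below the control mean in 5 of 5 mulberry arrays; the exact permutation p was 0.0317, or 0.357 after adjustment. Mulberry 1 and mulberry 5 had the lowest means (-0.60 and -0.45), and without them the mean was -0.19 and the median -0.19 (adjusted p = 4.2e-04). The mean of all arrays was -0.38 within scan day 1, -0.20 within scan day 2 and -0.45 within slide 3. With the scan day as a block the median was -0.30 (adjusted p = 5.4e-05), and with the slide as a fixed block it was -0.56 and no longer past the threshold (adjusted p = 0.152). Hepatocyte markers were lower by about as much under the main scaling with the days pooled. Their mean differed by -0.36 ± 0.19, and relative to them the cholesterol synthesis mean differed by 0.03 ± 0.12. Within scan days 1 and 2 the hepatocyte mean was -0.16 and -0.48. That was a smaller fall than in the cholesterol list on day 1 and a larger one on day 2.

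Genes that regulate sterol uptake also tended to lower values, short of the threshold. The mean of the 15 sterol regulation and uptake genes was -0.17 ± 0.05 (SE over arrays), and all 5 mulberry arrays lay below all 5 controls, an exact permutation p of 0.00794. That is the smallest p the design can give, and after adjustment over the lists it was 0.214. The separation was not complete under quantile normalization, where mulberry 1 (-0.09) and mulberry 5 (0.01) lay above control 1 (-0.12). Camera gave an adjusted p of 0.0533, and the median over members was only -0.03, with 9 members lower and 6 higher. The lower members included Insig1 (-0.81 ± 0.26), a sensor that retains the sterol-regulatory factors. Srebf2, which codes for the main activator of the pathway, was at -0.01 ± 0.19, a value of either sign depending on the scaling. The mean was -0.18 within scan day 1, -0.15 within scan day 2 and -0.22 within slide 3. Relative to hepatocyte markers it differed by 0.19 under the main scaling with the days pooled (adjusted p = 0.564 by permutation). Within scan day 1 these genes fell about as much as hepatocyte markers (-0.18 against -0.16), and within scan day 2 less (-0.15 against -0.48).

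**Figure D1:**
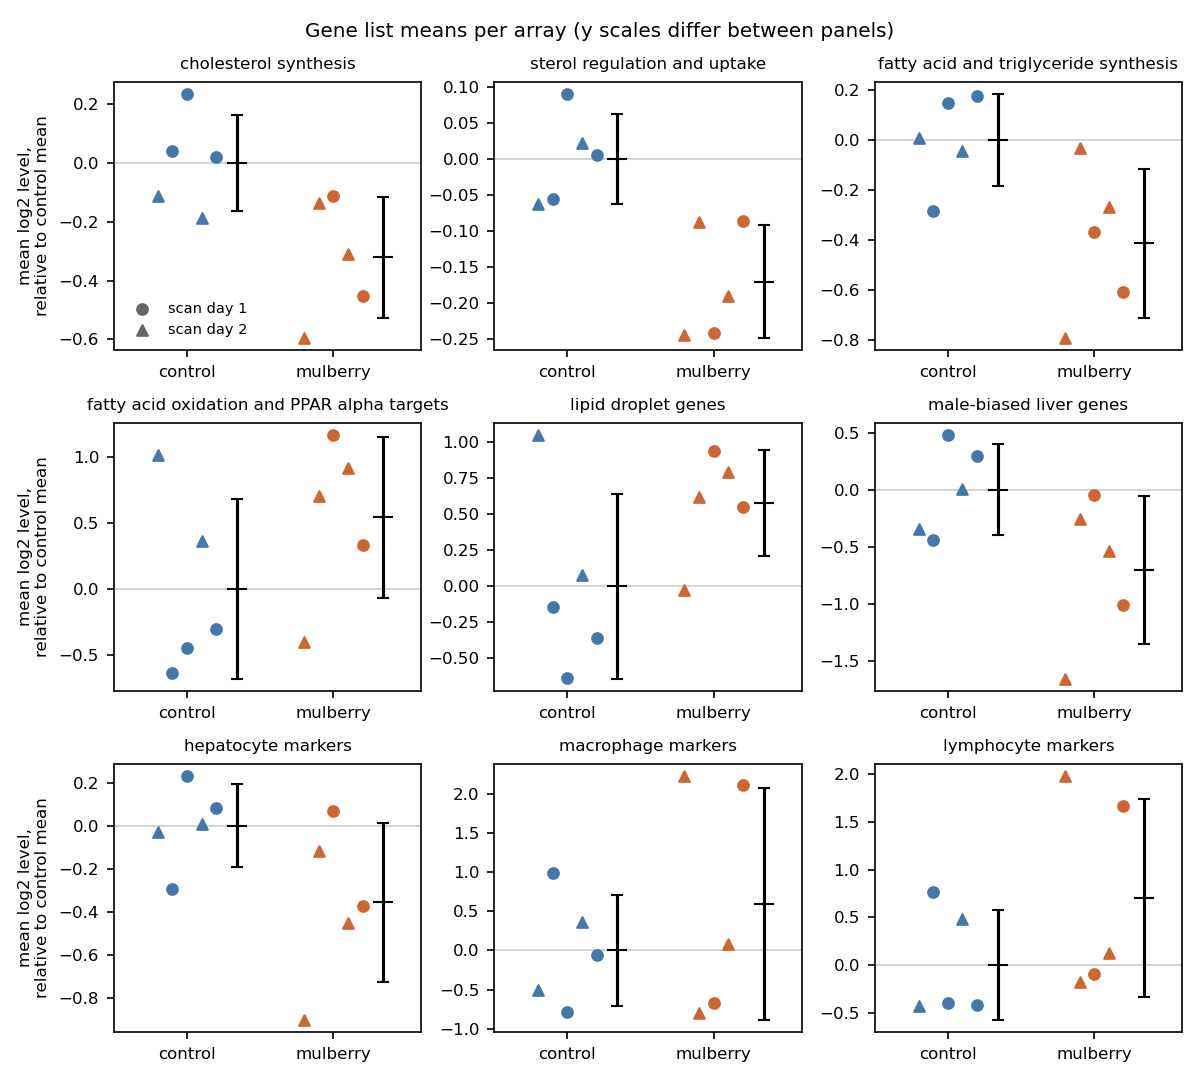
Mean log2 level of 9 gene lists on each array, relative to the control mean of the list (y axis, own scale per panel), for 5 control and 5 mulberry arrays; circles are scan day 1, triangles scan day 2, and bars give the group mean ± SD. For cholesterol synthesis all 5 mulberry arrays lie below the control mean, and for macrophage markers mulberry 1 and mulberry 5 stand at 2.23 and 2.11, above every other array.

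**Figure D2:**
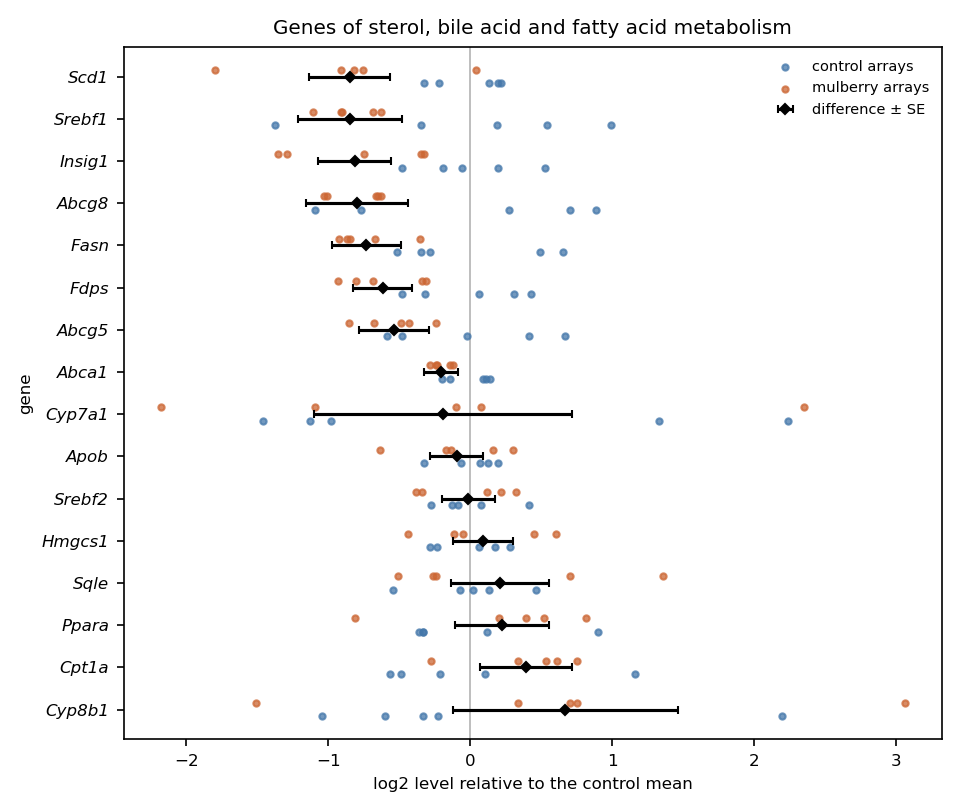
Log2 level of 16 genes of sterol, bile acid and fatty acid metabolism on each array relative to the control mean (x axis), with controls in blue, mulberry in orange, and diamonds for the mean difference ± SE. Scd1 and Srebf1 have the largest differences below 0 (-0.85 each), and Cyp7a1 and Cyp8b1 vary over several log2 units in both groups.

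Genes of sterol export and bile acids were lower as groups under the main scaling. Of 14 sterol efflux and LXR target genes 9 were lower (median -0.08, mean -0.19 ± 0.10). Camera gave an adjusted p of 0.0468, and an adjusted p of 0.401 with an estimated correlation; under quantile normalization the median was 8.6e-05 and the list was not past the threshold. Abcg5 (-0.54 ± 0.25) and Abcg8 (-0.80 ± 0.36), which form the canalicular sterol exporter, and the exporter Abca1 (-0.21 ± 0.12) were on the lower side. The largest differences in this list were in Scd1 and Srebf1 (-0.85 each). Both also belong to the fatty acid and triglyceride synthesis list, so the sterol efflux list is not separate from it. Of 18 bile acid genes 16 were lower (median -0.22; adjusted p = 0.00260, or adjusted p = 0.492 with an estimated correlation), among them the bile salt export pump gene Abcb11 (-0.71 ± 0.27). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.19 ± 0.91 and Cyp8b1 at 0.67 ± 0.79, so that neither difference exceeded the spread between mice. Of 16 lipoprotein genes 14 were lower (median -0.19; adjusted p = 0.0110, or adjusted p = 0.532 with an estimated correlation), while Apob was at -0.10 ± 0.19. Without mulberry 1 and mulberry 5 the median was 0.04 for the bile acid list, -0.01 for the lipoprotein list and -0.24 for the sterol efflux list (adjusted p = 6.8e-04).

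Most genes of fatty acid synthesis were lower on average, and most genes of fatty acid oxidation and lipid storage higher, with mulberry. In the fatty acid and triglyceride synthesis list 18 of 22 members were lower (median -0.37, mean -0.41 ± 0.16), in 5 of 5 mulberry arrays relative to the control mean. Thrsp, a lipogenic regulator, was at -1.55 ± 0.46, Srebf1 at -0.85 ± 0.37, Scd1 at -0.85 ± 0.28 and Fasn at -0.73 ± 0.24. Camera gave an adjusted p of 2.2e-06 and, with an estimated correlation, an adjusted p of 0.401. Mulberry 1 and mulberry 5 had the lowest means (-0.79 and -0.61), and without them the median was -0.13 and the mean -0.22 (adjusted p = 0.00164). Relative to hepatocyte markers the mean differed by -0.06, so a fall beyond that of hepatocyte genes was not seen under the main scaling with the days pooled. Under quantile normalization the synthesis means of mulberry 1 to 5 were -0.63, -0.07, -0.43, -0.22 and -0.50. The hepatocyte means were -0.44, -0.15, -0.13, -0.17 and -0.20, less low on all of these arrays but mulberry 2. The relative difference was not tested under that scaling. The synthesis mean of all arrays was -0.50 within scan day 1, -0.34 within scan day 2 and -0.77 within slide 3. The hepatocyte mean was -0.16, -0.48 and -0.89 there. The synthesis list thus fell further than hepatocyte markers on day 1 and less far on day 2. In the fatty acid oxidation and PPAR alpha list 26 of 28 members were higher (median 0.38), including the hormone gene Fgf21 (2.09 ± 0.86) and the thioesterase gene Acot2 (1.38 ± 0.64), with Cpt1a at 0.39 ± 0.32 and Ppara itself at 0.22 ± 0.33, a value below 0 after normexp correction. In the lipid droplet list 15 of 16 were higher (median 0.49), including Cidec (2.05 ± 1.05), Plin4 (1.07 ± 0.48) and Cidea (0.94 ± 0.25), which code for droplet coat proteins. Camera gave adjusted p values of 3.8e-06 and 7.5e-06 for the pair, and adjusted p values of 0.492 and 0.458 with an estimated correlation. The list means differed by 0.54 ± 0.41 and 0.58 ± 0.33 (SE over arrays), with exact permutation p of 0.222 and 0.127. The size of the difference varied with the scan day. The oxidation mean differed by 1.21 within day 1, by -0.28 within day 2 and by -1.09 within slide 3, and the lipid droplet mean by 1.12, -0.10 and -0.59. The values below 0 depended on single arrays. On day 2 the oxidation means were -0.40, 0.70 and 0.92 for mulberry 1, 2 and 4 and 1.02 and 0.36 for control 1 and 4. Leaving out mulberry 1 or control 1 thus turns the sign, to a difference far smaller than that of day 1. Slide 3 held mulberry 1 and both of these controls. Without mulberry 1 and mulberry 5 the medians were 0.70 (adjusted p = 7.7e-10) and 0.76 (adjusted p = 8.7e-05). With the scan day as a block the medians were 0.32 (adjusted p = 7.1e-05) and 0.42 (adjusted p = 9.9e-05). After normexp correction the oxidation list was not past the threshold (adjusted p = 0.125).

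Transcripts typical of male hepatocytes were lower with mulberry. Of 13 male-biased liver genes 13 were lower (median -0.66, mean -0.70 ± 0.34), with Hsd3b5 at -2.37 ± 0.90, Selenbp2 at -1.003 ± 0.32 and the complement gene C8b at -0.91 ± 0.24. Of 13 hepatocyte markers 13 were lower (median -0.38), such as Tat (-0.70 ± 0.25), which codes for tyrosine aminotransferase, and Ass1 (-0.57 ± 0.20) of the urea cycle. Camera gave adjusted p values of 2.7e-07 and 3.8e-06, and adjusted p values of 0.401 and 0.443 with an estimated correlation. The male-biased mean was -0.64 within scan day 1 and -0.65 within scan day 2, and the hepatocyte mean -0.16 and -0.48; within slide 3 they were -1.50 and -0.89. Mulberry 1 and mulberry 5 had the lowest male-biased means, -1.66 and -1.01, and without them the medians were -0.18 and -0.14. Drug-metabolizing enzymes (30 of 37 lower, median -0.24), glucose metabolism (16 of 21, median -0.20) and the acute-phase response (21 of 27, median -0.20) passed camera in the same direction with adjusted p values of 7.8e-04, 0.00694 and 0.00694; each had an adjusted p of 0.492 with an estimated correlation, and none of these 3 passed under quantile normalization. Without mulberry 1 and mulberry 5 their medians were -0.10, -0.05 and -0.41, and the glucose list was not past the threshold (adjusted p = 0.0630). The acute-phase fall was not shared by all mulberry arrays. Its mean was 0.49 in mulberry 1 and 0.51 in mulberry 5, and -0.64, -0.45 and -0.55 in mulberry 2, 3 and 4. Controls ran from -0.41 to 0.53. Between the groups the acute-phase mean differed by -0.13 ± 0.31, with an exact permutation p of 0.683.

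Markers of immune cells were higher in 2 mulberry livers and not in the other 3. The macrophage marker mean, relative to controls, was 2.23 in mulberry 1 and 2.11 in mulberry 5, against -0.80, -0.67 and 0.08 in mulberry 2, 3 and 4 and a control range from -0.79 to 0.99. Lymphocyte markers stood at 1.99 and 1.67 in mulberry 1 and mulberry 5 and at 0.13 or lower in the other mulberry arrays. As groups, 22 of 23 macrophage markers (median 0.63) and 17 of 17 lymphocyte markers (median 0.72) were higher, with Lyz2 at 1.20 ± 0.95, Gpnmb at 1.08 ± 0.94 and the T cell gene Cd2 at 1.11 ± 0.60. Camera gave adjusted p values of 0.00151 and 4.1e-06, and adjusted p values of 0.596 and 0.401 with an estimated correlation; the list means differed by 0.59 ± 0.73 and 0.70 ± 0.53. Without mulberry 1 and mulberry 5 the medians were -0.40 and -0.13. The cell cycle list (median 0.32, Mki67 1.12 ± 0.78) and the stellate cell and fibrosis list (median 0.26, Col1a1 0.99 ± 0.75, the gelatinase gene Mmp2 1.30 ± 0.48, the elastase gene Mmp12 -1.58 ± 0.48) passed camera with adjusted p values of 0.0274 and 0.0411, and had an adjusted p of 0.596 each with an estimated correlation. Without the same 2 arrays their medians were -0.11 and -0.27. Within scan days 1 and 2 the macrophage mean differed by 0.68 and 0.57 and the lymphocyte mean by 0.81 and 0.62, since each day held 1 of these arrays. Endothelial markers differed by 0.01 ± 0.11 (median -0.05; adjusted p = 0.948).

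**Figure D3:**
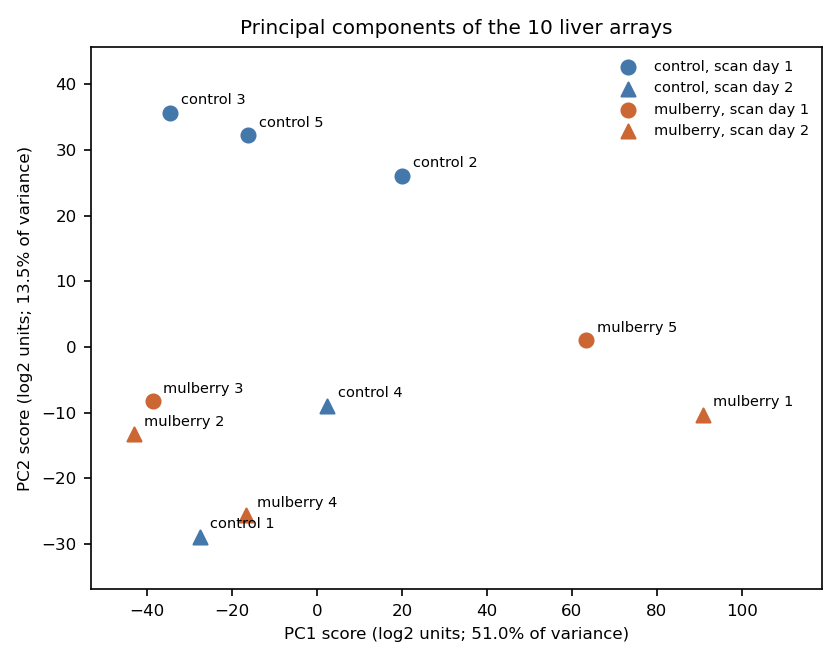
Principal component scores of the 10 arrays over the 17847 genes tested (PC1 on the x axis, 51.0% of variance; PC2 on the y axis, 13.5%), with controls in blue, mulberry in orange, circles for scan day 1 and triangles for scan day 2. Mulberry 1 and mulberry 5 stand apart on PC1 (90.9 and 63.4, other arrays at 20.1 or lower), and control 2, 3 and 5, which shared slide 1, have PC2 scores of at least 26.1.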

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

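A single array stood far from the other 4 of its group in 9 of 180 sets of 5 values examined, where about 9 are expected by chance. The sets were 27 list means and 63 genes in each group. For each, the gap to the nearest other array is given as a share of the range of the group, and no explanation was tested.

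Control 1 was the outlying array for 2 genes of bile acid synthesis and the clock. It had the highest control level of Cyp8b1 (-1.10 against -4.35 to -3.52, a gap of 0.747) and the highest of Dbp, an output gene of the circadian clock (2.38 against -0.34 to 0.39, a gap of 0.732). The same array had the highest control means of the fatty acid oxidation list (1.02) and the lipid droplet list (1.05).

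Mulberry 2 had the highest mulberry levels of Thrsp (2.59 against 0.37 to 0.65, a gap of 0.874) and Siglecg (-2.18 against -2.83 to -2.68, a gap of 0.765). Control 2 had the lowest control level of Siglecg (-3.82 against -3.41 to -3.26, a gap of 0.725). Mulberry 1 had the lowest mulberry level of Plin4 (2.14 against 3.69 to 4.19, a gap of 0.756), and mulberry 5 the lowest of the elastase gene Cela2a (-6.17 against -4.65 to -4.35, a gap of 0.835). Mulberry 3 had the lowest mulberry level of the elastase gene Cela1 (-5.05 against -4.18 to -3.94, a gap of 0.786) and the highest of Sdf2l1, a chaperone partner of the endoplasmic reticulum (3.62 against 2.51 to 2.69, a gap of 0.836).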

How the results depend on the processing

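The fits within scan days or slide 3, without mulberry 1 and 5, with a random slide block, by permutation, and relative to hepatocyte markers were chosen after seeing the data. The gene count stayed at 0 except for 1 gene each with array weights and without mulberry 1 (Rnf208 both times) and without mulberry 1 and 5 (1.96 ± 0.17, ENSMUST00000073543, named after its value was seen), so that leaving out 1 array gave 0 to 1. Genes at unadjusted p under 0.05 numbered 550 to 1308 without 1 array, 1995 under median scaling (which moved the median of all genes to -0.17), 2688 with array weights, 3629 with the slide as a fixed block, 1567 with no filter, 608 in the series table, 1743 without mulberry 1 and 5, 324 within scan day 2 and 3213 within slide 3. Of 1756 values of named genes under alternatives, 72 had the other sign. The dim gene Mmp13 moved from -1.96 to 0.02 after normexp correction.

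The number of lists past camera, 18, was 10 under quantile normalization, in the series table and within scan day 1, and 0 with an estimated correlation, by fry, by permutation of list means and relative to hepatocyte markers; without 1 array it was 14 to 19. All of these zeros came from tests that allow for members of a list varying together between arrays, beyond the preset 0.01. The means relative to hepatocyte markers were tested by permutation too, so that zero does not isolate the hepatocyte reference. The permutation test can give no p under 0.00794, which left little room to pass after adjustment over the lists (smallest adjusted p = 0.214). The cholesterol synthesis difference was below 0 under all alternatives but 1. It was not past the threshold with the slide as a fixed block or within slide 3 (-0.56 each), with an estimated correlation or by fry (-0.34 each) or by permutation (mean -0.32), and it was 0.034 relative to hepatocyte markers. Adjusted p over its alternatives ran from 4.8e-09 to 0.817.

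Medians or means with the other sign, cause not tested, were as follows for lists past the threshold in at least 1 of the fits compared; lists past it in neither, such as the clock and the female-biased list, also changed sign, 44 times in all. Relative to hepatocyte markers: acute phase 0.23, bile acids 0.14, bile duct 0.16, drug metabolism 0.12, endoplasmic reticulum stress 0.16, glucose 0.15, lipoproteins 0.18 and sterol efflux 0.17. With the slide as a fixed block and within slide 3 alike, which rest on the same 3 arrays: acute phase 0.16, bile duct 0.28, endothelial 0.41, fatty acid oxidation -0.93, interferon 0.69 and lipid droplets -0.75. Within scan day 1: cell cycle -0.055 and lipoproteins 0.0089. Within scan day 2: bile duct 0.11, endothelial 0.16, fatty acid oxidation -0.30 and lipid droplets -0.17. Without mulberry 1 and 5: bile acids 0.039, cell cycle -0.11, endoplasmic reticulum stress 0.021, lymphocyte -0.13, macrophage -0.40 and stellate -0.27. Bile duct was 0.089 after normexp and sterol efflux 8.6e-05 under quantile normalization. Sterol regulation, whose median lay near 0, ranged from -0.10 to 0.0078 without 1 array and was 0.0019 without mulberry 1.

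The replicate numbers of the scanner tables showed no pairing of the mice. Pairing by the control numbers of the deposited series table was not examined. Deviations from the group means of same-numbered arrays correlated with r from -0.44 to 0.41 across genes, and 0 of 5 controls correlated best with their own number. With the replicate block the gene count was 0, with 942 genes at unadjusted p under 0.05, and 17 lists passed, 16 of them among the 18.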

Other observations

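Of the 10 measured pancreatic acinar markers 7 were higher and 3 lower with mulberry, and the elastase genes went both ways: Cela3b was at 1.09 ± 0.23, Cela1 at 0.81 ± 0.32 and Cela2a at -0.74 ± 0.34. All were dim. Cela3b and Cela1 were well above background on 1 of 5 control and 4 of 5 mulberry arrays, and Cela2a on 5 of 5 and 2 of 5. Cela3b was the single member past the threshold adjusted over the list alone (0.00654), and the list did not pass camera (median 0.21, adjusted p = 0.199). Bile duct markers had a median of -0.15 (adjusted p = 0.0411, or adjusted p = 0.492 with an estimated correlation), with 7 of 10 members lower, Krt8 (-0.65 ± 0.21) and Cdh1 (-0.61 ± 0.18) among them. The endoplasmic reticulum stress list had a median of -0.24 (adjusted p = 0.0110, or adjusted p = 0.492 with an estimated correlation), with Sdf2l1 at -0.72 ± 0.24 and Dnajc3 at -0.54 ± 0.17. Its mean was 0.06 within scan day 1 and -0.44 within scan day 2. Without mulberry 1 and 5 its median was 0.021 and it did not pass camera (adjusted p = 0.214). The endothelial gene Lyve1 was at 0.39 ± 0.23.

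The remaining lists did not pass camera with all arrays. They were the antioxidant list (median -0.13, adjusted p = 0.0821), the interferon response (-0.07, 0.258; Gbp2 0.80 ± 1.13, Isg15 -0.49 ± 0.32), the clock (-0.05, 0.448; Dbp 0.70 ± 0.45), immediate early genes (-0.10, 0.258; Egr1 -0.86 ± 0.29, Nr4a1 -0.75 ± 0.34) and red cell markers (-0.10, 0.268; Alas2 -0.58 ± 0.25). Without mulberry 1 and 5 the interferon (median -0.52, adjusted p = 1.8e-09), antioxidant (-0.17, 6.8e-04) and immediate early (-0.37, 4.4e-04) lists passed, all lower. So did the endothelial (-0.11, 0.00257) and sterol regulation (-0.06, 0.00569) lists, and the acinar list passed with higher values (0.55, 0.00674). Like the other list p values without these arrays, they come from camera with the preset correlation alone. The 2 arrays left out had high interferon means (0.64 and 0.82), so their removal itself lowered that list. Mulberry 2, 3 and 4 (-0.50, -0.62 and -0.54) lay within the control range of -0.71 to 0.90. For female-biased liver genes (adjusted p = 0.997; Acot3 1.34 ± 0.65) the median was -0.05 and the mean 0.08, and for endothelial markers the mean and the median also differed in sign. With 4 members measured, adipocyte markers were not tested (median 0.24; Car3 -1.49 ± 0.57).

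The control columns of the deposited series table carried other replicate numbers than the scanner tables. Across 12178 shared genes, each mulberry column correlated best with its own array (r of at least 0.940, on deviations from the mean over arrays). The control columns matched another control array in each case: columns 1 to 5 followed arrays 5, 1, 2, 3 and 4, with r of at least 0.891, and correlated with their own arrays at r of -0.04 or lower. The group comparison is not affected by an order within the group.

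The tests of normalization, slide, cell share, scan day and hepatocyte genes that follow were chosen after the results were seen. Mulberry 1 and mulberry 5 had high macrophage and lymphocyte markers. After quantile normalization the lower of them still stood 1.15 above the highest control (control SD 0.74), which argues against array brightness. The lower of them stood 1.75 above the highest array of the same slides, which argues against the slide. Macrophage markers exceeded endothelial markers by at least 1.95 in both (control SD of that difference 0.75), which argues against a lower hepatocyte share that raised all other cell types alike. An immune reaction in these 2 livers, or a difference in the sampled piece, may be involved and stays open, as does an effect of the extract in some animals, which the other 3 mulberry arrays did not show.

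The lower cholesterol synthesis mean persisted with scan day as a block (-0.29 ± 0.11), which argues against scan day as its whole cause. The block cannot separate slide 1, with controls alone, from slide 2, with mulberry alone, so the slide stays open. Control means were 0.04, 0.24 and 0.02 on slide 1 and -0.11 and -0.19 on slide 3. Mulberry means ran from -0.60 to -0.11. Relative to hepatocyte markers the difference was 0.034 ± 0.12 under the main scaling with the days pooled, so the fall may be one shared with hepatocyte transcripts at large. That match depended on the scaling. Under quantile normalization the cholesterol means of mulberry 1 to 5 were -0.48, -0.21, -0.18, -0.30 and -0.38. The hepatocyte means were -0.44, -0.15, -0.13, -0.17 and -0.20, less low on each array. Among controls the order went both ways, and the relative difference was not tested under that scaling. Within scan day 1 the list fell more than hepatocyte markers (-0.38 against -0.16), and within scan day 2 less (-0.20 against -0.48). An effect of the extract on sterol genes themselves stays open as untested.

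For the higher fatty acid oxidation mean, scan day as the whole cause stays open. Both days held both groups, and the difference was 0.54 ± 0.41 without and 0.46 ± 0.42 with scan day as a block, so the block moved it little but it was about as large as its SE. The difference below 0 within day 2 depended on single arrays, mulberry 1 (-0.40, with mulberry 2 and 4 at 0.70 and 0.92) or control 1 (1.02). The controls of day 2 stood at 1.02 and 0.36 and those of day 1 between -0.63 and -0.30, with 2 or 3 arrays of a group per day.

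Other splits of the arrays into 5 and 5 were drawn, 100 in all with the real one. The gene count says nothing about chance here, because all 100 splits must reach the real count of 0 genes; the highest of the others was 7. For genes at unadjusted p under 0.05, 34 splits gave at least 924, up to 4417, so chance cannot be excluded for that count. The split along scan days called 7 genes, the most of any split drawn, which points to a structure of the samples; with scan day as a block the real comparison called 0. For the number of lists past camera under the main scaling, 2 of 100 splits, the real one among them, reached 18. The other splits gave 0 to 18, and 10 was a frequent count among them. That would put chance under the 0.05 level only if arrays were exchangeable. The structure along scan days goes against that, so the splits cannot exclude chance for the count or for any single list. The same limit holds for the permutation p values of the list means. Slides 1, 2 and 4 each held 1 group, so the splits do not exclude the slides. The count was 10 under quantile normalization and in the series table, where no splits were run.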
